A study of Caenorhabditis elegans with 2 samples.

How the data were processed

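ChIP-seq of eGFP-tagged NHR-28 was done on 2 biological replicates of whole C. elegans larvae at stage L3, per the labels' protocols, which also give a library size range of 150 to 350. The labels name nhr-28 as the antibody target and eGFP-nhr-28 as the tagged protein. A possible control experiment is named in the labels and was not analysed here. Peaks and background regions were called by the authors from the alignments of each replicate, and of both replicates pooled, against a control, and a final set was kept by the irreproducible discovery rate (IDR), per the deposited file list. The aligner, the peak caller, the IDR version and its threshold are not given in the sources used here.

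Each deposited list was in the narrowPeak layout, in builds ce10 and ce11, with regions of 1 width per list. The replicate lists held 30000 regions each, the pooled ce11 list 20876 and the final ce11 list 162. The signal of each region is as the authors deposited it. Its scale is not stated, so signals were used only to rank or describe regions within 1 list, and replicate signals were compared by rank or on a log2 scale and never averaged. The deposited −log10 of the q value was used to describe the lists. Candidate lists include background by construction, with q values of up to 0.961 in the pooled ce11 list. The summit was the middle of each region in every list. Depth per sample is unknown, since the lists hold no read counts, so no interval based on depth is given, and binomial intervals cover the counting of peaks only.

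Build ce11 lists were annotated with Ensembl release 115 for WBcel235, the same assembly as ce11, and with its reference sequence. The largest region end lay within the chromosome length for each nuclear chromosome. Build ce10 lists were used only for counts and overlaps, and no coordinate was converted. Coordinates are given from base 1. Some gene names stand for several annotated copies, which were counted as separate genes.

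The replicates were compared by the overlap of their 162 strongest regions (at least 1 bp, 1000 circular shifts, mitochondrial regions included) and by Spearman and Pearson correlation across the final peaks with 1000 bootstrap draws. Position classes were tested against 10000 circular shifts of the summits within chromosomes, two-sided, with Benjamini-Hochberg adjustment over 9 classes. Each summit was assigned in the order promoter, exon, intron and intergenic, and the small RNA classes were counted apart. The small RNA window was the same as the promoter window (1000 bp upstream to 500 bp downstream) and was set after peaks near such genes had been seen. Chromosome shares were tested with the exact binomial test, gene lists with Fisher's exact test, motifs with the exact McNemar test against both flanks (the larger p kept), and signal by class with 100000 permutations. A threshold of 0.05 was applied to adjusted p values. A peak between divergent genes counted for both.

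The gene lists, the motifs, the tests and the rule for named items were fixed before the data were examined. Named were nhr-28 and unc-119, the 20 strongest final peaks with the nearest TSS within 2000 bp, up to 4 bound members per gene list in order of signal, and the 3 strongest regions per replicate list that overlapped no final peak. The remaining ribosomal protein genes were named after their values were seen. The splits of X against autosomes, the alternatives without X, without mitochondrial regions, with lettered ribosomal protein names and with small RNA windows outside promoters, and the tests against matched promoters were also chosen after the data were seen. Alternatives fixed beforehand were the ce10 lists, the 81 strongest peaks, other promoter windows, overlap rules, list lengths and backgrounds, the loci of nhr-28 and unc-119 left out, and each replicate left out in turn. Leaving out a replicate meant taking the 162 strongest nuclear regions of the other replicate.

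The statistics were tested on simulated data, 40 sets each of 160 peaks (120 genes for the lists). With 40 of 160 random peaks moved into promoters, the promoter test called 97.5% of sets, and it called 0% of random sets. With 6 ribosomal protein genes added, the list test called 100% of sets, and random genes gave a call for any list in 0%. With 16 peaks placed at CTGCGTCTC, the motif test called 100% of sets and random positions gave 0%. With 20 shared regions, the overlap test called 100% of sets and independent lists gave 2.5%. The median test called 5% of sets without a difference and 100% with a difference of 0.5 on the log2 scale. The chromosome test called any chromosome in 2.5% of sets placed at random genes. It called X in 100% of sets of random positions with 30% of peaks moved to X. X then held 41.25% of peaks on average, so power at the observed share of 21.6% was not tested. Nor were random genome positions tried for this test without such a move. The bootstrap interval held the true correlation in 92.5% of sets. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.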

Results

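The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for NHR-28, a nuclear hormone receptor of the nematode Caenorhabditis elegans. The receptor carried an enhanced green fluorescent protein (eGFP) tag and was expressed from the transgene wgIs317 in strain OP317. This strain has the mutation unc-119(ed3), and unc-119 is the gene commonly used to rescue and select transgenic worms. Whole larvae of stage L3, of mixed sex, were used, and the series held 1 group of 2 biological replicates from separate biosamples. No second condition was present, so the comparisons were between replicates, between peaks and shifted genome positions, and between groups of genes. The read depth of each library was unknown, because the lists give no counts. Peak signals are the authors' own values per peak, those of the final peaks coming from pooled reads, so they have no SD or n.

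The final set held 162 peaks on build ce11 that passed the authors' threshold on the irreproducible discovery rate (IDR). Most of the 20 strongest peaks lay on the X chromosome outside promoters, and the autosomal ones among them lay in promoters, some of them of ribosomal protein genes. The strongest peak of all lay between genes on chromosome X from 9465672 to 9466011, with a signal of 169.9. Peak signals ran from 32.8 to 169.9 with a median of 40.9, and every peak was 340 bp wide. The 162 peaks were the 162 strongest of the 20876 candidate regions called on the pooled reads. The authors' list for build ce10 held 158 peaks. The smallest q value in the ce11 set was 0.00592, which 85 peaks shared, and the largest was 0.0175. A pair of peaks on chromosome II overlapped each other (15025606 to 15025945 and 15025806 to 15026145).

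**Figure D1:**
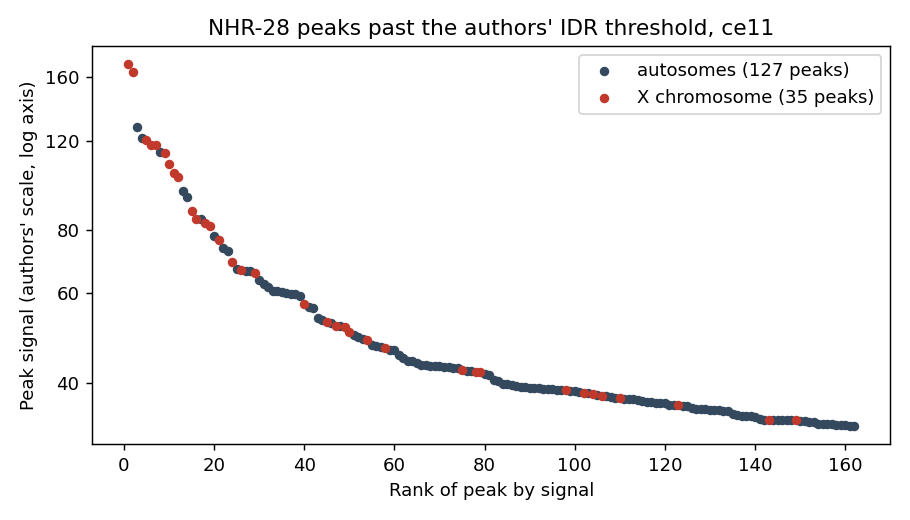
Peak signal on the authors' scale (log axis) against the rank of the peak, for the 162 peaks on ce11, each point being 1 peak. The 35 peaks on X (red) include 13 of the 20 strongest, and the 127 autosomal peaks (dark) fill most of the lower ranks.

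Among the 20 strongest peaks, 13 lay on X and 7 on autosomes. All 7 autosomal peaks had their summit in a promoter window, defined as 1000 bp upstream to 500 bp downstream of a protein-coding transcription start site (TSS), whereas 1 of the 13 X peaks did. Ribosomal protein genes took 3 of the nearest starts on the autosomes. The peak at rpl-3 (chromosome III, 3867390 to 3867729) had a signal of 127.6 and its summit 294 bp upstream of the TSS. The peak at rpl-15 (chromosome IV, 654745 to 655084) had a signal of 95.3, and that at rpl-35 (chromosome III, 7854542 to 7854881) a signal of 77.7. The other 4 autosomal peaks had as nearest genes Y17G9B.5, which shares its peak with rpl-20 (chromosome IV, 4749892 to 4750231, signal 121.2), cdc-48.1, which encodes an AAA ATPase (chromosome II, 10563408 to 10563747, signal 114.1), ZK1248.17 (chromosome II, 5844740 to 5845079, signal 92.8) and tasp-1 (chromosome III, 10759095 to 10759434, signal 83.9). The summit of the ZK1248.17 peak also lay at the spliced leader RNA gene sls-2.1.

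On X, the single promoter peak among the strongest belonged to puf-9, a gene for a Pumilio-family RNA-binding protein (5841128 to 5841467, signal 81.6, summit 294 bp upstream of the TSS). A further 5 X peaks had a TSS within 2000 bp, with the nearest genes F19H6.5 (signal 117.7), F55G7.5 (108.2), fbxb-58 (87.3), T27A8.7 (84.1) and F20B6.9 (82.7). The remaining 7 had no protein-coding TSS within 2000 bp. They lay at 9465672, 11094017, 2996965, 806503, 8036231, 6296355 and 16681970, given as start positions on X, with signals of 169.9, 163.7, 120.2, 117.7, 113.3, 103.8 and 101.8 in that order. The summits starting at 2996965 and 6296355 were in introns of Y41G9A.17 and mom-1, and the others were intergenic. All 20 peaks ranked 44 or better in replicate 1 and 21 or better in replicate 2.

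The replicates shared regions far more often than shifted lists did. Among the 162 strongest regions of each replicate, 58 of replicate 1 (35.8%) overlapped one of replicate 2 by at least 1 bp. After 1000 circular shifts of replicate 2 within chromosomes, the mean was 0.169 shared regions and the highest value 3 (one-sided permutation test, p = 0.000999, the smallest the shifts can give). Of the 162 final peaks, 51.2% were among the 162 strongest regions of replicate 1 and 73.5% among those of replicate 2. Their median rank was 136 in replicate 1 and 87.5 in replicate 2. Replicate 1 ranked its weakest match 20517 of 30000, and replicate 2 ranked its weakest match 2883.

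Across the 162 final peaks, the signals of the overlapping replicate regions had a Spearman rho of 0.31 (95% bootstrap interval 0.14 to 0.46) and a Pearson r of 0.49 on the log2 scale (0.35 to 0.61). These are correlations across peaks, which are not independent replicates and had been selected on their pooled signal. Split by chromosome after the data were seen, rho was 0.66 (0.43 to 0.83) for the 35 X peaks and 0.11 (-0.09 to 0.32) for the 127 autosomal peaks. Pearson r on the log2 scale was 0.58 (0.38 to 0.77) on X and 0.31 (0.10 to 0.49) on autosomes. The median pooled signal was 57.3 on X and 39.0 on autosomes, the latter nearer the weakest peak at 32.8. The selection on pooled signal may therefore bear differently on X and on autosomes. In the 81 strongest peaks rho was 0.55.

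**Figure D2:**
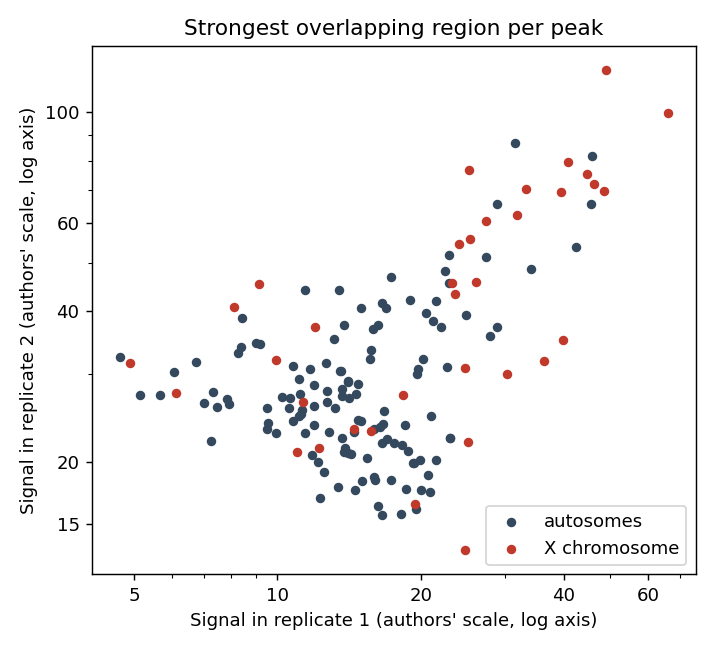
Signal of the strongest overlapping region in replicate 2 against that in replicate 1, both on the authors' scale with log axes, each point being 1 of the 162 peaks. Pearson r on the log2 scale is 0.58 for the X peaks (red) and 0.31 for the autosomal peaks (dark).

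Of the regions absent from the final set, the 3 strongest of replicate 1 were mitochondrial, starting at 646, 5614 and 11368, with signals of 201.5, 172.5 and 163.4. Its 3 strongest nuclear ones lay in an intron of F09A5.3 (chromosome X, 13145255 to 13145604, signal 19.6), at a tRNA gene and 750 bp upstream of F28H6.8 (chromosome X, 14134919 to 14135268, signal 19.3), and 422 bp upstream of the heat shock gene hsp-1 (chromosome IV, 17278362 to 17278711, signal 19.1). Replicate 2 had no mitochondrial region. Its own 3 strongest lay 211 bp upstream of metr-1, the methionine synthase gene (chromosome II, 10926180 to 10926519, signal 32), in a coding exon of tatn-1, a tyrosine aminotransferase gene, with sprr-2 as the nearest TSS (chromosome X, 14792351 to 14792690, signal 31.9), and between genes on chromosome X from 6253768 to 6254107 (signal 29.2).

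Peak summits were concentrated in promoters, near small nucleolar and small nuclear RNA genes and, with X included, near tRNA genes. They were sparse in exons and introns. Of the 162 summits, 90 (55.6%, exact 95% interval 47.6 to 63.4) lay in a promoter window, against 31.6% ± 3.66 (SD over 10000 circular shifts). The two-sided permutation p was 0.0002, the smallest these shifts can give, and the adjusted p over 9 position classes was 0.00045. Exons outside promoters held 4.32% of summits against 19.1% after shifting (adjusted permutation p = 0.00045), and introns held 13% against 24.4% (adjusted permutation p = 0.0012). Intergenic sequence held 27.2% against 24.8% (adjusted permutation p = 0.619). This share pools X and autosomes. With X left out, a choice made after the data were seen, it was 17.3%, below that of its shifted positions (adjusted permutation p = 0.228).

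Among small RNA genes, 12 summits (7.41%) lay near a small nucleolar RNA gene against 0.485% after shifting, and 7 (4.32%) near a small nuclear RNA gene against 0.162%. Both adjusted permutation p values were 0.00045. These classes overlap the promoter class, since 9 of the 12 and 5 of the 7 summits also lay in promoter windows of protein-coding genes. Among the 12, 4 were the peaks of rpl-15, iff-2, rps-12 and rpl-7A, and the overlapping pair on chromosome II counts as 2. In tests chosen after the data were seen, other genes' promoters at the same distances from the TSS gave 0.524% near small nucleolar RNA genes, against 10% of the 90 promoter summits (one-sided permutation p = 0.000999, the smallest possible). Near small nuclear RNA genes they gave 0.2% against 5.56% (permutation p = 0.000999). Outside promoters, 3 and 2 summits of these classes were left (1.85% against 0.311% and 1.23% against 0.101% after shifting, adjusted permutation p = 0.0447 for both). The small nuclear RNA class included 4 genes of the sls-2 family, which encode the spliced leader RNA SL2 that is joined to downstream messages of operons (sls-2.1, sls-2.2, sls-2.4 and sls-2.8, named after their values were seen). Near tRNA genes lay 8 summits (4.94%) against 0.828% (adjusted permutation p = 0.00108), and 7 of the 8 were on X. With X left out, a choice made after the data were seen, the tRNA share was 0.787% (adjusted permutation p = 1), and in the 81 strongest peaks the adjusted p was 0.121. Near microRNA genes lay 3 summits (1.85%, adjusted permutation p = 0.0548), at mir-354, mir-52 and mir-241, named after their values were seen. The microRNA class passed the threshold of the permutation test in the 81 strongest peaks (adjusted p = 0.0117), without replicate 1 (0.0072), without replicate 2 (0.0087) and without X (0.0279). None of the 162 summits lay near a ribosomal RNA gene, which allows a share of up to 2.25% (upper exact 95% limit).

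**Figure D3:**
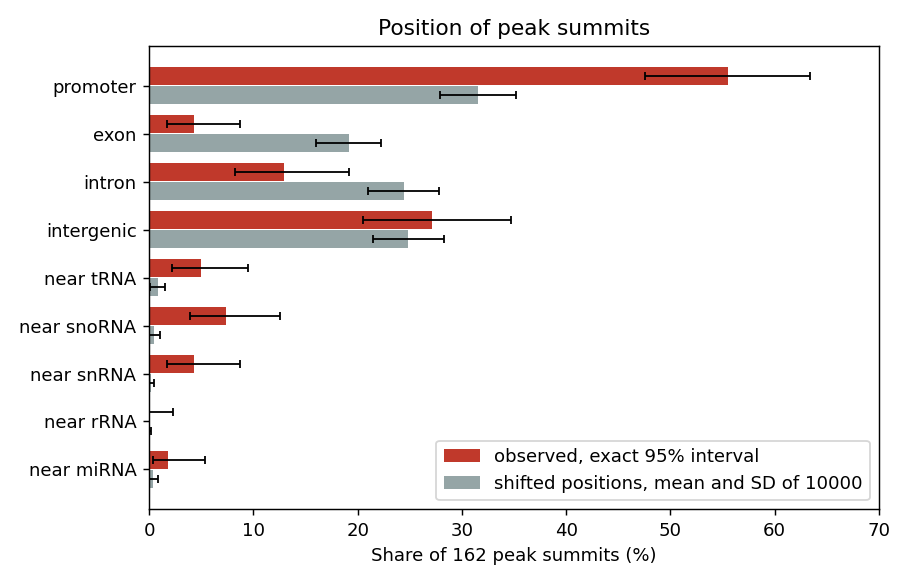
Share of the 162 peak summits in each position class (red, with exact 95% intervals) and the mean share after 10000 circular shifts within chromosomes (grey, with SD). The observed promoter share of 55.6% lies above the shifted 31.6%, and the observed exon share of 4.32% lies below the shifted 19.1%.

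X peaks lay in promoters less often than autosomal peaks and had a higher median signal. X held 35 of the 162 peaks (21.6%, exact 95% interval 15.5 to 28.7) and 13.7% of the protein-coding genes (two-sided exact binomial test, adjusted p = 0.0341 over 6 chromosomes). The other 5 chromosomes did not pass the threshold, and the lowest adjusted p among them was 0.224. Measured against sequence, however, X makes up 17.7% of the nuclear genome and held 18.4% of the lower-ranked pooled regions, and the 21.6% did not differ from that 18.4% by Fisher's exact test (p = 0.308). The X share was highest among the strongest peaks. It was 65% in the strongest 20 peaks (Fisher's exact p = 5.83e-06 against the lower-ranked regions, as in the next tests, which were chosen after the data were seen). Among the next 61 peaks it was 23% (exact p = 0.406), and in the weakest 81 it was 9.88% (exact p = 0.0598). The 81 strongest together had 33.3% (exact p = 0.00133). Without replicate 2, X held 29.6% (exact binomial test against its share of genes, adjusted p = 7.37e-07).

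Promoter windows held 7 of the 35 X summits (20%, exact 95% interval 8.44 to 36.9) and 83 of the 127 autosomal summits (65.4%, 56.4 to 73.6). These shares differed by Fisher's exact test (p = 2.02e-06, chosen after the data were seen). Shifted X positions gave 26.7% (permutation p = 0.486) and shifted autosomal positions 32.9% (permutation p = 0.0002, the smallest possible). The median distance to the nearest TSS was 1679 bp on X and 382 bp on autosomes. The median signal was 57.3 on X and 39.0 on autosomes, a difference of 0.55 in median log2 signal (two-sided permutation test, p = 5e-05). Promoter peaks and other peaks had median signals of 40.9 and 40.6, a difference of 0.01 on the log2 scale that did not pass (two-sided permutation test, p = 0.93). In the 81 strongest peaks this difference was -0.28 (permutation p = 0.0419), promoter peaks being the weaker class there. That value pools X, which held 33.3% of the 81, with the autosomes. Split over all final peaks, the difference was 0.07 on autosomes (permutation p = 0.186) and -0.53 on X (permutation p = 0.376). The 81 strongest peaks were not split, so the part of X in the -0.28 was not tested.

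Genes of the protein synthesis machinery were over-represented among the genes with a summit in their promoter window, which were 0.596% of the 19973 protein-coding genes. Whether the signal at any of these genes depends on NHR-28 was not tested, since neither the control nor other factors were analysed. A gene is called bound here if a summit lay in its promoter window. Ribosomal protein genes were the main group, with 10 of 79 members bound (12.7%) against 0.548% of all other genes (two-sided Fisher's exact test, adjusted p = 1.14e-09 over 29 lists). The bound members of the fixed list were rpl-3, rpl-20, rpl-15 and rpl-35 in order of signal, followed by rpl-12, rps-19, rps-15, rps-20, rps-1 and rps-12, whose signals ran from 63.8 to 39.0. The name pattern of the fixed list left out rpl-7A and rpl-36.A, and rpl-7A was bound (chromosome IV, 4390528 to 4390867, signal 38.7, summit 108 bp upstream of the TSS). With these 2 genes added, a choice made after the data were seen, 11 of 81 were bound (13.6%, adjusted exact p = 5.19e-11). Translation factors had 3 of 38 members bound (7.89%, adjusted exact p = 0.0217). These were iff-2, an eIF5A gene (chromosome II, 8561242 to 8561581, signal 60.6), eif-3.C, a subunit of initiation factor eIF3 (chromosome I, 9979751 to 9980090, signal 56.1), and the elongation factor gene eef-2 (chromosome I, 9163397 to 9163736, signal 43.1).

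Chaperone genes had 3 of 60 members bound (5%, adjusted exact p = 0.04). They were cct-1, a subunit of the cytosolic chaperonin (chromosome II, 8185053 to 8185392, signal 44.7), hsp-90 (chromosome V, 14685559 to 14685898, signal 44.1) and hsp-110 (chromosome III, 8447007 to 8447346, signal 39.7). Each of these summits lay nearer the TSS of another gene, which was mig-5, C47E8.4 and the proteasome gene rpn-3 in that order. Chemoreceptor genes were bound less often than other genes, with 1 of 1364 members (0.0733%, adjusted exact p = 0.04), namely srh-2 (chromosome V, 731289 to 731628, signal 42.1). Against a background of the 4913 genes with a candidate region in both replicates, the ribosomal list passed (25% of 40 members, adjusted exact p = 5.46e-07), and translation factors (adjusted p = 0.0637), chaperones (0.221) and chemoreceptors (0.575) did not. Without replicate 1, translation factors (adjusted exact p = 0.154) and chaperones (0.285) did not pass. Chaperones also failed the exact test without replicate 2 (2 of 60, adjusted p = 0.251) and in the 81 strongest peaks (0.158). Chemoreceptors failed it in the 81 strongest peaks (adjusted exact p = 0.792), in a window of 500 bp upstream to 200 bp downstream (0.151) and without X (0.0519).

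Assigning each peak to its nearest TSS within 2000 bp gave other calls. It moved the peaks of rpl-20, rps-19, rps-15, rps-20 and rps-12 to other genes. The ribosomal list passed with 5 of 79 members (6.33%, adjusted exact p = 0.00415), and no chaperone gene was bound. Collagens passed with 5 of 175 members (2.86%, adjusted exact p = 0.0368), and hypodermis and seam markers with 2 of 20 (10%, adjusted exact p = 0.0404). The collagens, named after their values were seen, were col-90, dpy-13, sqt-1, sqt-3 and col-63, and dpy-13 and sqt-3 were also the 2 hypodermis markers. The summits at dpy-13 and sqt-3 lay 1616 and 1412 bp downstream of the TSS, and those at sqt-1 and col-90 lay 1334 and 1297 bp downstream.

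None of the members of the 6 tissue lists had a peak in the promoter window, that is 0 of 19 intestine markers, 0 of 20 hypodermis and seam markers, 0 of 16 body muscle markers, 0 of 16 pharynx markers, 0 of 25 neuron markers and 0 of 16 germline markers (exact p = 1 for each). With 0.596% of all genes bound, lists of this size could not have shown a depletion. Nuclear hormone receptor genes had 2 of 274 members bound (0.73%, adjusted exact p = 1), nhr-238 (chromosome V, 1629347 to 1629686, signal 41.4) and nhr-68, a regulator of propionate breakdown (chromosome V, 11572914 to 11573253, signal 39.8). The propionate and methionine list held nhr-68 as its only bound member of 18 (adjusted exact p = 0.592), and passed without replicate 1, where metr-1 was bound too (2 of 18, 11.1%, adjusted exact p = 0.0481). Of the fatty acid and lipid list, 0 of 98 genes were bound, and of the xenobiotic list, 0 of 199.

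In 5 further lists, none of which passed, a single member was bound. They were the proteasome with rpn-3 (1 of 33), the respiratory chain with cox-5A (1 of 45, signal 52.5), the insulin and ageing list with ins-39, an insulin-like peptide gene (1 of 59, signal 66.8), histones with his-37 (1 of 73, signal 53.2) and collagens with col-63 (1 of 175, signal 32.8). No member was bound of the lists of homeobox genes (0 of 85), bHLH factors (0 of 37), peroxisome genes (0 of 27), the vacuolar ATPase (0 of 21), autophagy and lysosome genes (0 of 46), hedgehog-related genes (0 of 85), molting and heterochronic genes (0 of 20), C-type lectins and lysozymes (0 of 256), neuropeptides (0 of 102) and major sperm proteins (0 of 31).

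**Figure D4:**
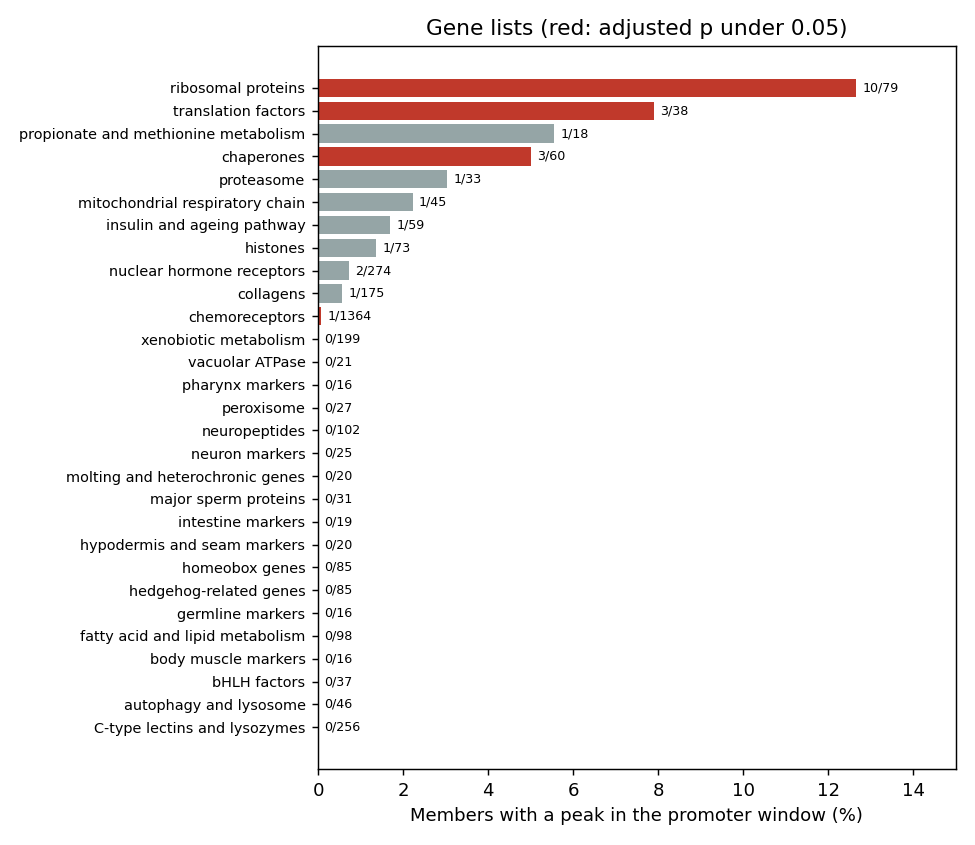
Share of each fixed gene list with a peak summit in the promoter window, with the number of bound and annotated members beside each bar. The 4 lists with an adjusted p under 0.05 (red) are ribosomal proteins (10 of 79), translation factors (3 of 38), chaperones (3 of 60) and, with a share below that of other genes, chemoreceptors (1 of 1364).

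Of 11 sequence patterns, CTGCGTCTC, an element of many worm promoters, was the one that passed. It occurred within 50 bp of 15 of the 162 summits (9.26%), and in 0 windows centred 500 bp to the left and 1 centred 500 bp to the right (exact McNemar test, adjusted p = 0.00134). Its carriers were 14 of 127 autosomal peaks and 1 of 35 X peaks. In the 81 strongest peaks the share was as high (9.88% against 0% of either flank), and with fewer peaks the adjusted exact p was 0.0859. The call was also lost without replicate 1 (6.17%, adjusted exact p = 0.129). The core site of nuclear receptors (AGGTCA or GGGTCA) matched 7.41% of summits and 4.32% of either flank (adjusted exact p = 0.726), and the direct repeat of this core with 1 base of spacing matched none. E-boxes (CACGTG) matched 8 summits against 0 and 1 flanking windows (adjusted exact p = 0.215), and passed without replicate 2 (adjusted exact p = 0.0286). GATA sites matched 15 summits against 23 and 18 flanking windows (adjusted exact p = 1), and GAGAGAGA matched 5 against 1 and 0 (adjusted exact p = 0.602). Runs of T matched 11 summits against 20 and 19 flanking windows (adjusted exact p = 0.556). Without replicate 2 the runs passed as a depletion, with 3.09% of summits against 12.3% and 14.2% of the flanks (adjusted exact p = 0.0143). The sites of PHA-4 matched 51 against 43 in either flank (adjusted exact p = 0.726). The DAF-16 site, the HNF4-type site and TGATAAG matched 7, 1 and 3 summits and had adjusted exact p values of 1.

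The tagged gene itself lay in a stretch of X without any candidate region. The gene nhr-28 (chromosome X, 16354976 to 16359650) had 0 regions within 20 kb in the replicate 1, replicate 2, pooled and final lists, where the average density on X would give 14, 14, 9.69 and 0.0882. The empty stretch ran from 16334304 to 16389799 in replicate 1 (55496 bp) and from 16333435 to 16392297 in replicate 2 (58863 bp). Each was the third widest of its list, whose median gaps were 1888 and 1855 bp. Besides nhr-28, the stretch held sur-7, ace-1, an acetylcholinesterase gene, and let-2, a type IV collagen gene. The region of unc-119 (chromosome III, 10902641 to 10908935) had 12, 16 and 10 regions within 20 kb in the replicate 1, replicate 2 and pooled lists, against 14.3, 14.6 and 10.3 from the average density, and none was in the final set.

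**Figure D5:**
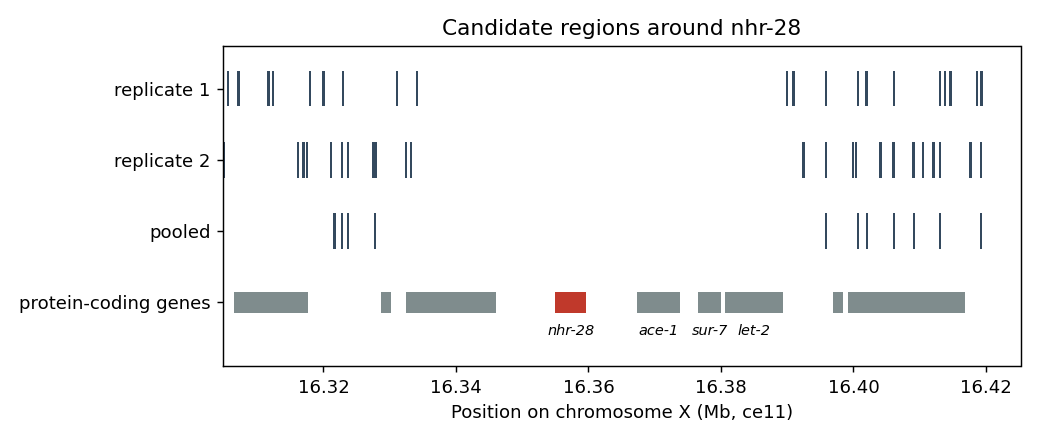
Candidate regions of replicate 1, replicate 2 and the pooled reads (dark bars) and protein-coding genes (grey, nhr-28 in red) along chromosome X on ce11, with positions in Mb. No list has a region between 16334304 and 16389799, and regions of all 3 lists lie on both sides.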

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

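Mitochondrial DNA lies outside the nuclear comparisons, and it gave a signal in a single replicate list. Replicate 1 held 16 mitochondrial regions, 15 of them among its 162 strongest, with signals from 7.46 to 201.5, and the replicate 2 and pooled lists held 0. With these regions left out, a choice made after the data were seen, 62 of the 162 strongest nuclear regions were shared between replicates, against 58 with them. No biological explanation was tested, since the design has 1 group.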

How the results depend on the processing

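Values under alternative settings were tallied without the ribosomal RNA class and without gene lists and motifs that passed under no setting. Of 147 values, 105 kept their direction and side of the threshold, stayed within their spread or, for counts, stayed near the main count. Another 14 kept their direction and lost significance, 7 kept it and gained significance, 9 moved and 12 reversed. Of those 12, 3 newly passed their threshold and 1 no longer did. The 9 that moved include the number of peaks itself, 81 against 162 in the 81 strongest, which that choice fixed in advance. Replicate overlap passed under all 7 alternatives, with 13.9% to 38.3% of regions shared, and promoter proximity passed under every alternative run. No final peak lay within 20 kb of nhr-28 or unc-119, so leaving out those loci tests nothing and is not counted. In the 81 strongest peaks, rho between replicates was 0.55 against 0.31, 2 chromosomes passed against 1, 2 gene lists against 4, and 0 motifs against 1, and 0% of the propionate and methionine list was bound against 5.56%. There the promoter minus other difference in median log2 signal, with X and autosomes pooled, was -0.28 (permutation p = 0.0419) against 0.01. Against genes with a candidate region in both replicates, 1 gene list passed, on a background of 4913 genes, and the collagen share was 3.23%. With 1 replicate left out, 1 to 2 chromosomes and 0 to 3 motifs passed, the promoter signal difference was -0.0487 to -0.0113, the propionate and methionine share was 0% to 11.1%, and the collagen share was 0.571% in both cases, as in the main result. With X left out, chosen after the data were seen, the intergenic share was 17.3%, below that of its shifted positions (adjusted permutation p = 0.228), and the collagen share was 0.571%. With the nearest TSS alone, 0% of chaperone genes, 2.86% of collagens and 10% of hypodermis and seam markers were bound. Apart from the smaller peak number and the smaller background, the cause was not tested. The unknown read depth limits what the replicate ranks can show. No paired analysis was possible because the series has 1 group.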

Other observations

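On the X peaks, the tests of the 20 strongest peaks, of promoter shares and of the MEX motif were chosen after the result was seen. The counts and tests at small RNA genes, the tests of chance spacing and transgene copies at nhr-28, and the count with rpl-7A moved were chosen likewise. Short sequence words at the summits had been scanned before the X motif was chosen.

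Of the 8 peaks near tRNA genes, 7 lay on X, which holds 45.1% of the annotated tRNA genes (exact binomial p = 0.0266, not adjusted). X had 1 of the 12 peaks near small nucleolar RNA genes and 9.54% of those genes, and 0 of the 7 peaks near small nuclear RNA genes and 2.33% of those (exact p = 1 for both). A pair of peaks (ranks 68 and 89) counted in more than 1 of these classes. Within the spliced leader genes, 4 of 18 annotated sls-2 genes and 0 of 12 sls-1 genes had a summit within 200 bp. The sls-1 genes encode the leader SL1. The peak at mir-241, a let-7 family microRNA gene, had a signal of 42.7 and its summit 320 bp downstream of the annotated start.

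The strong X peaks were the pattern that stood apart. Over-representation of X at every rank is argued against, since X held 18.4% of the lower-ranked regions against 17.7% of the nuclear genome. The 65% of the 20 strongest peaks on X is the pattern itself, so its difference from 18.4% (Fisher's exact p = 5.83e-06) adds no support. Promoter binding is argued against by the promoter share of 20% on X and 65.4% on autosomes (Fisher's exact p = 2.02e-06). Repeated sequence is argued against for most X peaks by a median of 100% unique 31-base words, the same as in autosomal peaks. Under 90% unique were 6 of the 35 X peaks and 11 of the 127 autosomal peaks, so repeats stay possible for those few. A candidate explanation is that some of the strong X peaks are recruitment sites of the dosage compensation complex. Such sites are known to carry a motif (MEX) with the core GCGCAGGG. Words at the summits had been scanned before this motif was chosen, so its p values are not an independent test. The core occurred in 11 of 35 X peaks (31.4%, exact 95% interval 16.9 to 49.3), in 0.14% of shifted X positions (one-sided permutation p = 0.0001, the smallest possible) and in 0 of 127 autosomal peaks (Fisher's exact p = 1.17e-08). What stays open is whether the signal depends on NHR-28 at all, since 8.57% of X summits had a nuclear receptor core site (AGGTCA or GGGTCA), against 1 and 0 of the 35 flanking windows (exact p = 0.625), the receptor's own site is not known here, and neither the control nor other factors were analysed.

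The motif core lay close to the summits, at a median distance of 27 bp for the nearest match in each of the 11 peaks. The 11 peaks with the core had a median signal of 101.8 and the 24 other X peaks 48.5. This was a difference of 1.07 in median log2 signal (two-sided permutation test, p = 0.00181). Of the 13 X peaks among the 20 strongest, 7 carried the core, and the strongest peak of all did not. The second strongest peak had its nearest match on the minus strand at 11094226 to 11094233, 43 bp from the summit, within GGGAACCATTCGCGCAGGGACACCTCACTG, and another, 58 bp from the summit, at 11094125 to 11094132. The peak starting at 2996965, in an intron of Y41G9A.17, had it on the minus strand at 2997123 to 2997130 within TTAAATTTATCGCGCAGGGAGGAAGTAGCC. The peak starting at 8036231 had it on the minus strand at 8036401 to 8036408 within AATTTTTTATCGCGCAGGGACGTATGTCGA. Its summit lay 4912 bp upstream of the TSS of xol-1, the switch gene of sex determination and dosage compensation, which is named here after its position was seen. The sequences above are given as read on the strand of the core. X holds 81 matches of the core, and the autosomes hold 233.

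The empty stretch around nhr-28 was the second pattern. Chance spacing is argued against, as 0 of 175742 windows (0%) of 44675 bp on X outside the stretch had no region in either replicate. These windows overlap heavily, so their number is not a count of independent observations. The next widest gap on X was 40246 bp, with 29.9% unique words. Repeated or unknown sequence is argued against too, since 96.5% of its 31-base words were unique, against 91.3% in the genome, and it held 0 unknown bases. The other 2 gaps at least as wide lay on chromosome V in sequence of 1.2% and 1.29% unique words. There were 0 other gaps of that width in unique sequence, and the next widest there was 22129 bp. Whether extra transgene copies of the locus, raising the control or leading to removal of the region, account for it stays open. The locus of unc-119 was not empty, with 3 and 4 regions within 2 kb in the replicates and 12 and 16 within 20 kb, against 14.3 and 14.6 from the average density. That would count against extra copies only if the rescue copy came from the same species, which is not known here, and neither the control nor the caller's settings were analysed.

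The third pattern was CTGCGTCTC at promoter peaks. It occurred in 7 of the 90 promoter peaks (7.78%), against a mean of 0.797% over 1000 draws of other genes' promoters at the same distances from the TSS (one-sided permutation p = 0.000999, the smallest possible). The composition of other genes' promoters in general is thus argued against. The draws matched distance to the TSS only, so promoters alike in base composition or activity were not tested for CTGCGTCTC. Peaks of ribosomal protein and translation factor genes are argued against as its source, because 0 of the 13 promoter peaks of the fixed lists carried it and 7 of the other 77 did (9.09%, against 0.778% in matched promoters, permutation p = 0.000999, the smallest possible). With the peak of rpl-7A moved to the ribosomal side, 7 of the other 76 did (9.21%, against 0.757%, permutation p = 0.000999). The other 8 carriers were among the 72 peaks outside promoters, where no matched test was run. Whether NHR-28 or another factor is responsible stays open, since no other factor was analysed.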
